A study of Mus musculus with 10 samples.

How the data were processed

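Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 2 histone marks in the spleens of mice with leukemia. H3K4me3, trimethylation of histone H3 at lysine 4, lies mainly at active promoters, and H3K27me3, trimethylation at lysine 27, marks regions repressed by Polycomb proteins. Per the labels' protocols, the mice had received leukemic blasts from a transgenic model of acute promyelocytic leukemia by injection, which enlarged the spleen. Part of a spleen was fixed in formaldehyde, embedded in paraffin (FFPE) and sectioned, and is called tissue here. The rest was used as isolated cells that were fixed outside the animal, called cells here.

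Per the labels' protocols, the FFPE material was sonicated mildly at 50 W, digested with micrococcal nuclease and sonicated again at 100 W, while the last sonication of cells was at 50 W. Whether the cells were also digested is not clear from the protocol, part of which was not used here. Each immunoprecipitation (IP) took 260 to 600 ng of chromatin. The 10 libraries fall into 6 groups by their titles: H3K4me3 IP of cells and of tissue with 2 libraries each, H3K27me3 IP of cells and of tissue with 1 each, and input DNA of cells and of tissue with 2 each, of which 1 belongs to the H3K4me3 and 1 to the H3K27me3 experiment. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

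The authors deposited the aligned reads of each library, 35 bases each, and a peak list for each of the 6 IP libraries. Per the submitters' processing notes, reads were aligned with Bowtie to the mouse genome build mm9; the version and options are not given in the sources used here. Reads with equal position and strand occur in the files, so duplicates had been kept. Peaks were called with MACS for each IP library against an input, per the file headers, and not on pooled replicates. The score of each peak in the deposited lists is the authors' value, the negative log10 of the peak caller's p-value times 10, and the lowest score in each list lay at 50. It was used to rank and filter peaks within a list. Both H3K4me3 replicates of a preparation shared 1 input.

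Reads were counted here from the deposited alignments. A read was counted once per 5′ position and strand, and its 5′ end was moved 75 bp downstream. The most frequent distance between plus-strand and minus-strand ends was 81 to 108 bp over the libraries, so this went past the fragments' middle. In the H3K4me3 IP the distance was 94 and 95 bp in cells and 85 and 81 bp in tissue. Distinct reads ranged from 5518019 to 10455258 per library. Peaks of the 4 H3K4me3 lists were merged into regions where they touched or overlapped. Counts were scaled by size factors (median of ratios over regions), from 0.887 to 1.15, and given as RPM (reads per 1000000 distinct reads, written rpm). Tissue was compared with cells with limma 3.58.1 in R 4.3.3 (trended prior variance, two-sided) on log2(rpm + 0.5), in regions with at least 20 reads over the 4 libraries, with Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate changes of regions with few reads. In the main fit the prior degrees of freedom were infinite, so each standard error came from the variance trend over all regions. The spread of a region's own replicates had no weight of its own, and an SD printed beside a p-value does not set that p-value.

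The test on log values was fixed in advance for deposited reads and peaks without a count table, and no count model was run on the reads counted here. In simulated data with the real regions' means, 47 of 100 regions changed by a fold of 2 were recovered among 23343 regions. Of 100 changed by a fold of 4, 86 were recovered. There were 5 false calls, and no region was called when none was changed. All simulated regions had the same dispersion (spread beyond counting noise) of 0.00366. False calls among regions that differ in dispersion were therefore not measured. Replicates of a group differed by more than sampling noise in a chi-square over regions (1.38 per region in cells and 1.13 in tissue), so no pair looked like the same library deposited 2 times. This does not show that they are separate biological samples.

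The rule for the regions named in the text was fixed before the data were examined, as were the tests of the comparisons and most of the alternatives, while several tests of the closing section were chosen later and are named there. In each direction they are up to 8 H3K4me3 regions with the highest absolute log2 fold change among those past the threshold, with both tissue libraries beyond both cells libraries and a mean of at least 20 reads in the higher group. For H3K27me3 they are the 6 regions in both lists with the highest mean score and, in each direction, the 5 merged regions with the highest absolute log2 ratio among those with at least 50 reads in the higher library and a peak there. Regions outside these rules are said to have been chosen after their values were seen. The gene annotation at hand belongs to another build than mm9 and was not used here. The planned comparisons of promoters and of gene lists were therefore not run, and regions are named by mm9 coordinates counted from 1.

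Peaks were called shared where they overlapped by 1 bp or more, and the overlap after moving 1 list by 50 or 100 kb in either direction gave the share reached by chance. Read density was compared over 10 kb bins and over merged regions as log2(rpm + 0.5), by Pearson's r across bins or regions, which are not independent replicates. Shares carry 95% Wilson intervals and single-region read counts exact Poisson intervals. Both cover counting error only, since PCR copies cannot be told from independent molecules. With 2 libraries against 2, an exact permutation test of a single value cannot go below a two-sided p of 0.33, and single values are therefore given without a test. H3K27me3 had 1 library per preparation and no test.

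Alternatives covered duplicate reads, scaling, pseudocount, limma with voom weights, read minimum, read shift, input subtraction, choice of regions, each replicate left out, a block for the replicate number, the overlap rule, the score minimum, bin width and depth. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The counting and overlap steps were tested on simulated data.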

Results

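The series asked how ChIP-seq from FFPE spleen sections compares with ChIP-seq from cells isolated from the rest of the same spleen. The 10 libraries held 6633894 to 11940639 aligned reads. Duplicate reads made up 11.5% and 11.2% of the H3K4me3 IP of cells, 8.88% and 7.07% of that of tissue, 13.4% of the H3K27me3 IP of cells and 35.8% of that of tissue. The H3K4me3 lists held 19782 and 18239 peaks in cells and 16426 and 19739 in tissue, covering 10.4 to 13.02 Mb. The H3K27me3 lists held 46552 peaks in cells, over 27.9 Mb, and 48235 in tissue, over 17.4 Mb. H3K27me3 peaks were narrower in tissue, with a median of 295 bp against 477 bp.

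H3K4me3 was compared between tissue and cells region by region. Of 22887 regions tested, 87 changed in limma at an adjusted p of 0.05, with 31 higher and 56 lower in tissue. The region on chromosome 13 from 23516429 to 23516779 had the highest change, with 2.88 ± 0.034 rpm in tissue against 0.25 ± 0.19 rpm in cells (SD, n = 2 each). Its log2 fold change was 2.20 (standard error 0.45, limma adjusted p = 0.00141), and it rested on 26 and 29 reads in tissue against 1 and 3 in cells. The region on chromosome 1 from 157887807 to 157888161 was higher in tissue by a log2 of 1.48 (standard error 0.38, limma adjusted p = 0.0357). On chromosome 5, the regions from 124933094 to 124933652 and from 124380407 to 124381170 were higher in tissue by 1.19 and 0.96.

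The other regions named for a rise in tissue lay on chromosome X from 91422932 to 91423663 (log2 1.18), on chromosome 9 from 32349714 to 32350303 (1.07), and on chromosome 8 from 97399301 to 97400497 (1.01) and from 73895108 to 73895944 (0.92). Among regions lower in tissue, that on chromosome 5 from 147072495 to 147072999 fell from 18.5 ± 1.21 rpm in cells to 7.90 ± 0.85 rpm in tissue (SD, n = 2 each). Its log2 fold change was -1.18 (standard error 0.14, limma adjusted p = 1.29e-13). The region on chromosome 19 from 61275468 to 61276121 fell from 14.2 ± 0.77 to 5.98 ± 0.088 rpm (log2 -1.18, limma adjusted p = 1.19e-10). That on chromosome 3 from 5860562 to 5860891 fell from 11.4 ± 1.47 to 5.32 ± 1.81 rpm (log2 -1.06, limma adjusted p = 5.05e-07). These 3 regions belong to 15 with input density over 10 times the median, of which 13 changed, all 13 of them lower in tissue. The region on chromosome 4 from 134862486 to 134863554 had a log2 fold change of -1.31, and those on chromosome 7 from 4675063 to 4676007 and on chromosome 2 from 181653086 to 181653560 both had -1.18. The regions on chromosome 15 from 74762392 to 74763386 and on chromosome 8 from 42126407 to 42127313 had -1.10 and -1.07.

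The count, its direction and most named calls moved with the libraries and the processing. Without cells replicate 1, 131 regions were higher and 137 lower in tissue, and without cells replicate 2, 60 and 35. Without tissue replicate 1, 1 was higher and 13 lower, and without tissue replicate 2, 0 and 7, so that 13 and 14 of the 16 named regions lost their call, among them all 8 named rises, with the direction of each kept. Without the regions of raised input 56 remained past the threshold, and scaling by all reads gave 453 higher and 18 lower, with the median region shifted by a log2 of 0.19. With the log2 of the own input subtracted, 1337 regions were higher and 8509 lower, and of the 16 named regions 5 kept their call, 9 lost it (that on chromosome 5 from 147072495 with its log2 fold change still at -1.17, limma adjusted p = 0.0501) and those on chromosome 8 from 73895108 and from 42126407 turned sign. The regions on chromosome 5 from 124933094 and from 124380407 then had log2 fold changes of 0.08 and 0.24 (limma adjusted p = 0.888 and 0.483), where the tissue input was itself higher by 1.11 and 0.72. That on chromosome 19 from 61275468 went to -0.32 (limma adjusted p = 0.594), where the log2 ratio of tissue to cells input was -0.86. With voom weights in limma, 10 of the 16 lost their call, among them the region on chromosome 13. Its log2 fold change was then 3.39 (limma adjusted p = 0.225), and 2.18 without either tissue replicate 1 or 2 (adjusted p = 0.714 and 0.692), so its call and not its fold was lost.

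**Figure D1:**
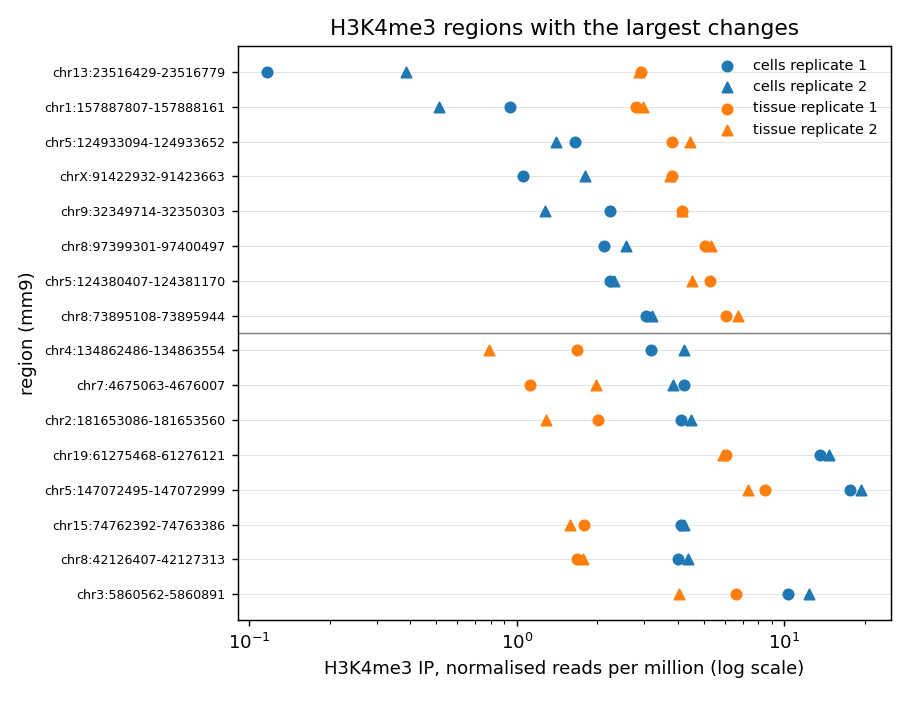
Normalised H3K4me3 IP signal in rpm, on a log axis, in the 8 named regions higher in tissue (above the line) and the 8 lower in tissue (below it). Each point is 1 library, blue for cells and orange for tissue, with circles for replicate 1 and triangles for replicate 2, and in every region both tissue libraries lie on the same side of both cells libraries.

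Most H3K4me3 regions found in both replicates of a preparation were found in the other preparation as well. Of 11322 regions found in both cells replicates, 73.9% were overlapped by those found in both tissue replicates, and of 9630 in tissue, 84.7% were overlapped by those of cells. Single lists overlapped less. Between replicates, 63.3% and 68.6% of the peaks were overlapped in cells and 63.2% and 53.7% in tissue, for replicates 1 and 2. Between single lists of the same replicate number, 53.01% and 61.4% of cells peaks were overlapped in tissue, and 61.3% and 55.8% of tissue peaks in cells. After moving 1 list, 2.34% of the peaks of cells replicate 1 were overlapped. Between both cells replicates the share rose with the score, from 16.5% (95% interval 15.4 to 17.7) among the lowest-scoring peaks of cells replicate 1 to 99.9% (99.8 to 100.0) among the highest. Between preparations, the share of both-replicate cells regions fell to 52.6% when a score of at least 100 was asked of every list. The share of both-replicate tissue regions overlapped by those of cells was then 84.5%. Fewer tissue peaks reached that score, 5520 and 7188 against 9283 and 8939 in cells.

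The merged lists gave 35457 regions, of which 22293 lay in 1 list and 7789 in all 4. The 7789 shared regions had a median width of 1249 bp. The 1277 regions in both cells lists and neither tissue list had a median of -0.26, and the tissue input held 2.01 times the read share of the cells input there. In the 7789 regions of all 4 lists that input ratio was 1.75. The 779 regions in both tissue lists and neither cells list had a median of 0.52, with an input ratio of 0.80. The fold changes of the 1277 and 779 regions follow from how these were chosen, and 16 and 4 of them passed the limma threshold. Their input ratios follow from that choice too, at least in part. Peaks had been called against the inputs, and a high input works against a peak.

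**Figure D2:**
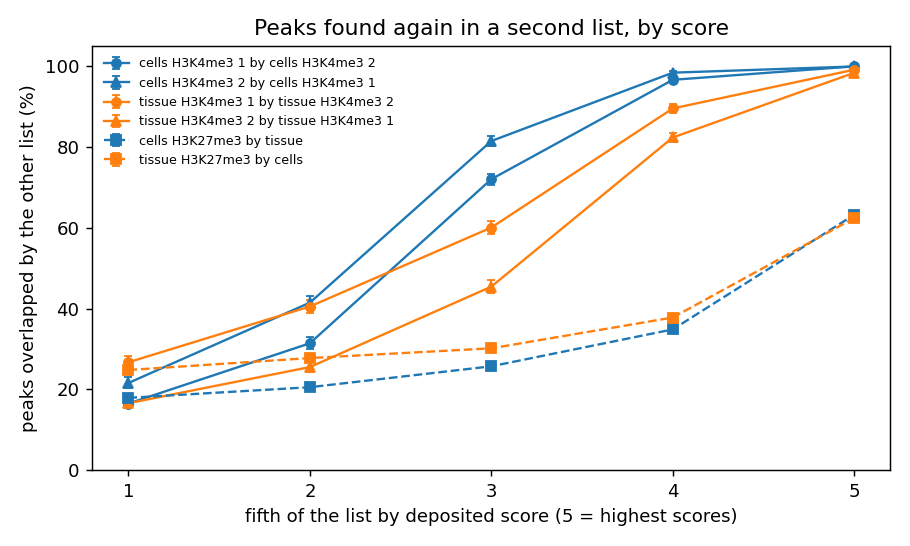
Percent of peaks overlapped by a second list, in 5 equal steps of the deposited score (1 lowest, 5 highest). H3K27me3 had no replicate pair, so the lines of the marks compare unlike pairs of libraries. Solid lines are H3K4me3 replicates and dashed lines H3K27me3 between preparations, blue for peaks of cells and orange for peaks of tissue, and bars are 95% Wilson intervals; the highest H3K4me3 points lie at 98.4% to 99.9% and the highest H3K27me3 points at 63.2% and 62.4%.

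H3K27me3 peaks were shared less often between preparations than those of H3K4me3. With 1 H3K27me3 library per preparation, the overlap within a preparation is unknown, and these shares have no replicate value beside them. A tissue peak overlapped 32.5% (95% interval 32.0 to 32.9) of the cells peaks, and a cells peak overlapped 36.6% (36.2 to 37.0) of the tissue peaks, against 10.8% and 11.5% after moving 1 list. With reciprocal overlap over 50% of both peaks, the shares were 15.2% and 14.7%. Shared bases were 25.4% of those covered in cells and 40.6% of those covered in tissue. Merging peaks within 3 kb gave domains of up to 97.9 kb in cells and 73.4 kb in tissue, with 34.5% and 34.0% of domains shared, against 15.7% and 15.4% after moving 1 list. Chromosome X carried 55 peaks in cells and 60 in tissue.

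The regions with the highest mean score had close H3K27me3 signal in both preparations. On chromosome 12 from 85907598 to 85914564, cells had 51.9 rpm (95% Poisson interval 47.1 to 57.0) and tissue 50.2 rpm (45.3 to 55.5), with inputs of 9.60 and 10.3 rpm. On chromosome 15 from 75831363 to 75837313, the values were 43.7 rpm (39.3 to 48.4) and 43.2 rpm (38.6 to 48.1). The log2 ratios of tissue to cells were 0.09 on chromosome 5 from 140383609 to 140388394, -0.04 on chromosome 12 from 85106710 to 85112164 and -0.08 on chromosome 15 from 78541610 to 78551423. On chromosome 12 from 112510602 to 112515793, cells had 45.0 rpm (40.54 to 49.82) and tissue 36.0 rpm (31.87 to 40.50), with intervals that do not overlap.

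Other regions were far apart in the H3K27me3 libraries. On chromosome 7 from 16539847 to 16541083, tissue had 7.30 rpm (5.52 to 9.48) and cells 2.66 rpm (1.67 to 4.03). The log2 ratio of tissue to cells was 1.23 on chromosome 2 from 30729679 to 30730921, 0.95 on chromosome 2 from 163680285 to 163681604, 0.85 on chromosome 4 from 154733735 to 154734723 and 0.84 on chromosome 13 from 49238708 to 49240318. In the last of these the tissue input was higher by a log2 of 1.21 and in that on chromosome 4 by 0.89, on 7 and 5 input reads against 1 in cells each. On chromosome 2 from 179832852 to 179834708, cells had 6.77 rpm (5.12 to 8.80) and tissue 2.22 rpm (1.29 to 3.55). The log2 ratio was -1.39 on chromosome 2 from 31694837 to 31696112, -1.23 on chromosome 15 from 101798749 to 101799929, -1.23 on chromosome 5 from 143181263 to 143182415 and -1.21 on chromosome 7 from 105504033 to 105505394. These differences compare 1 library with 1 and have no replicate check. The regions were picked for the largest ratios, which the Poisson intervals do not take into account, so intervals that lie apart are no test here.

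Across 75897 merged H3K27me3 regions, Pearson's r between cells and tissue was 0.625, and 9095 regions were at least 2-fold higher and 6205 at least 2-fold lower in tissue. These counts depend on the pseudocount of 0.5. A pseudocount of 2 gave 14 higher and 20 lower, and 0.1 gave 16566 and 11660. With 0.5, 9091 of the higher regions had a tissue peak only and 6196 of the lower ones a cells peak only. Such regions were chosen for a peak in that library alone, which by itself favours a higher signal there. In the 13883 regions with a peak in both lists r was 0.932, and 4 were 2-fold higher and 9 lower, which follows in part from how these regions were chosen, since a peak in both lists leaves out those that differ most. On the log2 ratio of IP to own input, r across all regions turned to -0.22. The 31435 regions with a cells peak only and the 30579 with a tissue peak only enter both values of r across all regions. How far their choice lowers r was not tested.

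ChIP enrichment was read from the share of reads in each library's own peaks. For H3K4me3 the share was 7.23 ± 0.071% in cells and 7.60 ± 0.91% in tissue (SD, n = 2 each). It was 5.03 ± 0.18 times the share of the own input in cells and 3.36 ± 0.11 times in tissue (SD, n = 2 each), a gap wider than the spread between replicates. Against the inputs of the H3K27me3 experiment, the ratios were 4.68 in cells and 5.34 in tissue, so the order turned with the input. For H3K27me3 the share was 11.8% in cells and 9.06% in tissue, which was 5.53 and 6.98 times that of the input. Over the merged H3K27me3 peaks of both lists the order turned, to 4.46 in cells and 4.24 in tissue.

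**Figure D3:**
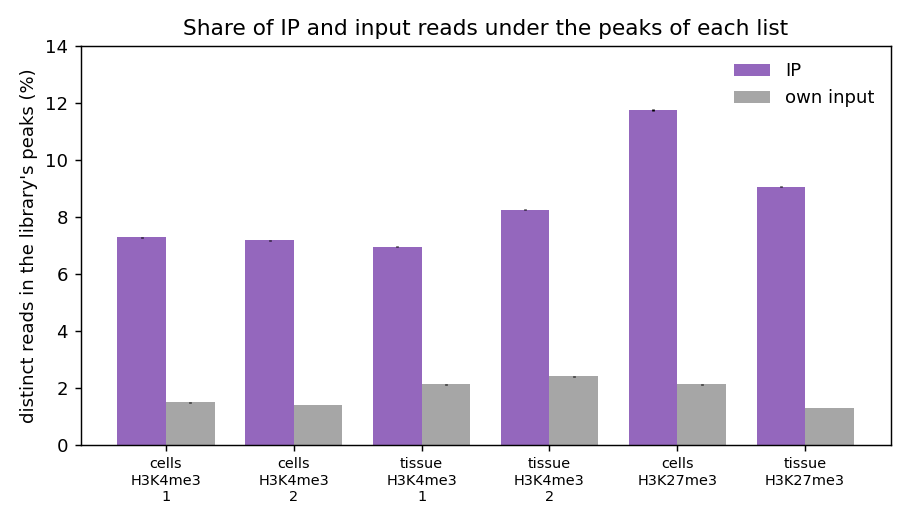
Percent of distinct reads lying in the peaks of each IP library, for the IP (purple) and its own input (grey), with 95% Wilson intervals that are narrower than the line ends. IP shares run from 6.95% to 11.8% and input shares from 1.3% to 2.39%.

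Read density over 10 kb bins was close in every H3K4me3 library, inputs included. The 4 H3K4me3 IP libraries had a mean r of 0.902 with the tissue input and 0.907 with the cells input of their experiment. For H3K4me3, r was 0.939 between cells replicates, 0.943 between tissue replicates and 0.936 on average over the 4 pairs of a cells and a tissue library (0.934 to 0.939). H3K27me3 in cells and tissue had r = 0.951. Pairs of an H3K4me3 and an H3K27me3 library had a mean r of 0.743. In merged H3K4me3 regions, r was 0.889 on average between cells and tissue IP and 0.891 between the tissue input and 0.853 between the cells input and the IP libraries, so these values do not measure likeness of the mark alone. These values are across bins, which are not independent.

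Few H3K4me3 regions carried an H3K27me3 peak. In cells, 589 of 11322 regions found in both replicates did (5.20%, 95% interval 4.81 to 5.63), against 5.70% after moving 1 list. In tissue, 252 of 9630 did (2.62%, 2.32 to 2.95), against 4.77%. Of the 589 regions in cells, 113 (19.2%, 16.2 to 22.6) overlapped such a region of tissue, and of the 252 in tissue, 111 (44.0%, 38.1 to 50.2) overlapped such a region of cells. In the H3K4me3 regions of all 4 lists, the H3K27me3 IP held 0.607 times the read share of its input in cells and 0.578 times in tissue. Bulk chromatin does not show whether both marks lie on the same nucleosome.

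Whether inputs were closer within an experiment or within a preparation depended on the measure. Over 10 kb bins, r was 0.925 between the cells and tissue inputs of the H3K4me3 experiment and 0.898 between those of the H3K27me3 experiment, but 0.862 between both cells inputs and 0.863 between both tissue inputs. In merged H3K27me3 regions these values were 0.701, 0.626, 0.649 and 0.655, in the same order. Thinned to the shallowest library they were 0.614, 0.610, 0.587 and 0.616 there, so depth accounts for part of that order. In merged H3K4me3 regions they were 0.834, 0.802, 0.7939 and 0.7935, closer within each experiment, as over bins. The tissue input of the H3K4me3 experiment had 3.70% of its reads in H3K4me3 regions, while the cells input of that experiment had 2.36% and the cells and tissue inputs of the H3K27me3 experiment 2.54% and 2.42%. With 2 inputs against 2, no exact permutation test can fall below p = 0.33.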

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

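The comparisons of the H3K27me3-experiment inputs, of shallower inputs and of bins chosen without the inputs were chosen only after their results were seen. Of 14 measures, 6 put all tissue libraries above all cells libraries in 1 experiment and below them in the other. Measures in which the H3K4me3 libraries of tissue and cells overlapped in range were not counted, whatever their means. None of these differences was tested, since the H3K27me3 experiment had 1 library of each kind. Duplicate reads in the IP were 2.67 times as frequent in tissue as in cells for H3K27me3 and 0.704 times for H3K4me3. IP over own input in the own peaks was 1.26 times that of cells for H3K27me3 and 0.669 times for H3K4me3. Both directions turned under an alternative, H3K27me3 to 4.24 in tissue against 4.46 in cells in merged peaks and H3K4me3 to 5.34 against 4.68 with the inputs of the H3K27me3 experiment. The unevenness of IP reads over 10 kb bins had ratios of 0.984 and 1.045. In the inputs, the ratio of duplicate shares was 0.684 in the H3K27me3 experiment and 1.41 in the H3K4me3 experiment. The ratio of input unevenness was 0.962 and 1.08, and that of the share of input reads in H3K4me3 regions was 0.955 and 1.57.

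The last of these is a pattern of the tissue input of the H3K4me3 experiment, which held more reads in H3K4me3 regions than the other 3 inputs. Depth by itself is argued against by both shallower inputs, which held at most 1.07 times the share of the cells input (thinning left the ratio at 1.57 but keeps shares by construction and decides nothing), and FFPE preparation by itself by the 0.955 of the H3K27me3 experiment. H3K4me3 IP fragments mixed into that input would make its excess over the cells input a constant share of the tissue IP's excess. The test fixed in advance went against this, with a ratio of -0.75 between the strongest and the weakest regions (95% bootstrap interval -0.79 to -0.71), but it decides nothing: the weakest regions had been called as peaks against that same input, which held 917 rpm there against 1718 rpm in the cells input. In 20000 bins of 1 kb ranked by cells IP reads alone, a test added with its outcome already known, the share was 17.4% to 19.5% at every level and the ratio 1.12 (1.02 to 1.22), so mixing may contribute but stays open, as do chromatin differences between the H3K4me3 sections and cells, which were not tested.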

How the results depend on the processing

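The values without regions of raised input, for regions in all 4 lists, with the other experiment's input and with a score of at least 100 were chosen after seeing the data. The planned promoter and gene-list tests were not run, for want of an annotation of mm9. The cause of a change below was not tested unless stated.

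The 87 H3K4me3 regions became 471 (453 higher, 18 lower) with scaling by all reads, 55 (16 and 39) without a read minimum, 452 (224 and 228) in regions found in both replicates of a preparation, and 56 (21 and 35) without raised-input regions. The last 2 tested 12072 and 22872 regions, against 22887 in the main fit. Fewer tests alone cannot account for the 452. The named region on chromosome 13 kept its log2 fold change of 2.20 in that fit, with a limma adjusted p of 3.91e-11. Its unadjusted limma p in the main fit was 8.65e-07, so its standard error was lower among the 12072 regions. How far choosing regions with a peak in both replicates lowered the estimated spread was not tested. Subtracting the log2 of the own input gave 9846 (1337 and 8509). By construction its counting noise enters both libraries of a preparation alike, and so adds to the difference but not to the replicate spread. Such noise favours no direction, while the median log2 fold change moved to -0.45. The tissue input held 3.70% of its reads in H3K4me3 regions against 2.36% in the cells input, and subtracting a higher tissue input lowers the difference by construction. With the own input subtracted, the regions on chromosome 8 from 73895108 and from 42126407 went to -0.59 and 0.20. Leaving out a replicate gave 7 to 268, with the lone library assumed to vary like the others. Limma with voom weights gave 80 (20 and 60). At least 100 reads gave 126 (48 and 78) and regions in all 4 lists 128. Of 245 alternative values of the 16 named regions, 170 kept direction and threshold, 73 kept direction only and 2 changed sign.

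Deviations of libraries with the same replicate number correlated at 0.000195. Samples paired by spleen could give as low a value where spleens differ little beyond counting noise, so this does not decide whether the numbers pair the samples. With the replicate number as a block, 67 regions were called (21 and 46).

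H3K4me3 overlap of both-replicate regions, cells in tissue and tissue in cells, was 63.5% and 74.6% with reciprocal overlap over 50% of both peaks and 67.0% and 81.2% in the higher-scoring 50% of peaks. Tissue in cells was 84.0% with overlap over 50% of the shorter peak. With a score of at least 100, cells in tissue was 52.6% and tissue in cells 84.5%. Using 1 replicate of each gave 53.01% to 61.4% and 55.8% to 61.3%. Between replicates, in cells and tissue, it was 61.8% and 61.9% over the shorter peak, 52.6% and 53.4% reciprocal, 82.3% and 79.1% in the higher-scoring peaks, 71.7% and 60.8% with equal numbers of peaks, and 83.9% and 82.9% with a score of at least 100. H3K27me3 overlap, cells and tissue, was 28.8% and 32.8% over the shorter peak, 15.2% and 14.7% reciprocal, and 34.5% and 34.0% in domains.

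Across H3K27me3 regions, r was 0.598 with all reads, 0.495 and 0.752 with pseudocounts of 0.1 and 2, and -0.22 for IP over own input, where regions 2-fold apart numbered 29599. With those pseudocounts they numbered 28226 and 34, since a higher pseudocount draws ratios towards 1 by construction.

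IP over input in cells and tissue H3K4me3 was 3.71 and 2.73 in merged peaks and 4.68 and 5.34 with the other input, and 3.51 in tissue with all reads. For H3K27me3 it was 4.46 and 4.24 in merged peaks, 5.60 and 7.16 with reads not moved, and 5.73 in cells with all reads. Density r between preparations, for H3K4me3 and H3K27me3, was 0.932 and 0.943 with all reads, 0.928 and 0.929 with a pseudocount of 0.1, 0.943 and 0.964 with 2, 0.719 and 0.788 in 1 kb bins, 0.990 and 0.993 in 100 kb bins, and 0.905 and 0.933 thinned to the shallowest library. H3K4me3 regions with H3K27me3 made up 3.11% and 0.893% in cells and tissue with overlap over 50% of the H3K4me3 peak and 1.95% and 1.12% in the higher-scoring peaks. Depth limits precision: the median tested region held 85 reads over 4 libraries, and the median standard error was 0.31 on the log2 scale.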

Other observations

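The tests of distinct reads, of ends 1 base apart and of other splits were chosen only after their results were seen, as were the regions named next. Where H3K27me3 domains of cells and tissue overlapped, they were joined into stretches longer than the domains of either preparation. The longest of these had close enrichment. On chromosome 15 from 102757382 to 102901341, a stretch of 144 kb, IP over input was 5.24 in cells and 5.37 in tissue. On chromosome 11 from 94924899 to 95047297 it was 4.48 and 4.39, on chromosome 5 from 139985687 to 140105145 3.92 and 4.00, on chromosome 4 from 140834202 to 140941108 3.91 and 4.42, and on chromosome 15 from 78478959 to 78579345 3.51 and 3.33.

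Read density on chromosome X, relative to the autosomes, was 0.276 to 0.316 in the inputs and 0.277 to 0.292 in the H3K4me3 IP, but 0.180 and 0.186 in the H3K27me3 IP of cells and tissue. Chromosome 12 had 1.29 to 1.39 in the inputs and H3K4me3 IP and 1.13 and 1.14 in the H3K27me3 IP. Of the 13 H3K4me3 regions of raised input that changed, 7 lay on chromosome 11 between 3031864 and 3100179, with log2 fold changes from -0.89 to -0.47. The region on chromosome 17 from 39979884 to 39985839, 5956 bp wide, had -0.93.

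Under 50% of the H3K27me3 peaks of each preparation were overlapped by the other. Lower enrichment in tissue was not seen at the shared peaks, where cells over tissue was 1.00 (1.0023). Those were chosen for a peak in both, so this value cannot decide. Unevenness over all 10 kb bins was 1.26 in cells and 1.24 in tissue, against 0.70 and 0.68 in their inputs. It argues against a large loss over wide stretches but says little on single peaks, with medians of 477 and 295 bp. Over merged peaks IP over input was 4.46 in cells and 4.24 in tissue, so a small loss stays open. Fewer distinct reads in tissue are argued against by a ratio of cells to tissue of 1.08. Signal below the peak caller's threshold in the other preparation stays open: at unshared peaks its median IP over input, relative to 10 kb away, was 1.12 (1.1154) in tissue and 1.12 (1.1188) in cells, between the limits set for and against, and the summed ratios were 0.993 and 0.976. A difference between sections and cells was not tested apart from preparation. Without H3K27me3 replicates, what libraries of the same preparation would share is unknown, so variation between any libraries stays open as well.

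Read ends fell on the same base in 2 libraries more often than at shifted positions. In the 21 pairs without a cells library of the H3K4me3 experiment this was 3.07 to 5.51 times as often, and in the 24 pairs with one 1.47 to 1.65 times. The tissue input of the H3K4me3 experiment had 5.42 and 5.51 with its IP replicates 1 and 2, and those IP libraries had 5.26 with each other. The remaining pairs of the 21 reached at most 4.14. Both sides of preferred nuclease cuts would put opposite-strand ends next to each other, but that ratio was 0.939, which leaves a nuclease that trims ends untested. The same molecules in both libraries predicted this low opposite-strand ratio, yet as the whole cause they are argued against by 2.28 at 1 base away. In the pairs among the tissue H3K4me3 libraries the value at 1 base away was 2.53, 2.62 and 2.40, against at most 2.44 in the remaining pairs. Their higher coincidence thus lay largely at the same base, and whether shared molecules add to it was not tested. Positioned nucleosomes may contribute, with 1.57 at 5 bases away, between the limits set for and against.

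The grouping into tissue and cells called 87 H3K4me3 regions in limma and the other two splits of the 4 libraries called 0 at most, with 399 and 417 regions at an unadjusted p under 0.05 against 2223. Each of the other splits puts a cells and a tissue library into each group. A difference between preparations then enters the spread within groups and lowers the calls by construction, so these counts do not measure what chance gives. Only 1 of the 3 splits called as many, and 3 splits are too few for a share under 0.05.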
